A study of Homo sapiens with 2 samples.

How the data were processed

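RNA-seq was compared between 1 library of Huh7 cells with a control shRNA and 1 library of Huh7 cells with an shRNA against USP22, grouped by the labels. Per the labels, total RNA was extracted with TRIZOL, cleaned and treated with DNase, and libraries were prepared with a kit for messenger RNA. The submitters' processing notes name HISAT2 2.0.4, StringTie 1.3.0 and the build GRCh37, without saying which step each served, and the annotation is not given in the sources used here.

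Each deposited table pairs gene symbols and Ensembl identifiers with 1 value per gene. The header names no unit. The values were read as FPKM, which is an assumption. They are not whole, which speaks against counts but not against TPM. Their sums of 244301 and 218955 over 11976 genes are only a weak pointer to FPKM, since the choice of genes is unknown. A plain ratio within a gene is the same in either unit up to 1 constant per library, and TMM and median centring were run as alternatives for that constant. The pseudocount of 1 and the filter at a mean of 1, given below, are fixed in size. Ratios of low genes, the genes kept and the counts therefore do depend on the unit. How the 11976 genes were chosen is not given in the sources used here, and genes outside them are not analysed here. Of the values, 54 in the control and 49 in the USP22 shRNA library were listed at 0, 11 of these genes in both. For 7 symbols on 2 rows, the row with the higher mean was taken in the gene lists.

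Depth was looked for in the low values, where whole read counts would leave equal steps once values are multiplied by transcript length. Over 4000 candidate step sizes the best strength was 0.0465 in the control over 2181 values, and 77 of 100 shuffles of the lengths gave at least as strong a step. In the USP22 shRNA library it was 0.0725 over 1554 values, against a highest of 0.0734 and a median of 0.0618 over the shuffles, 3 of which were at least as strong. A step that weak was not taken as a read count in either library, so depth is unknown and no count model was used.

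From the deposited FPKM, the log2 ratio of each gene was computed as log2 of (USP22 shRNA + 1) over (control + 1), which understates the ratio of low genes. Genes with a mean of at least 1 FPKM over the 2 libraries were kept (10195 genes), and a gene was counted as higher or lower at a log2 ratio of at least 1 in size, a rule of size with no test. The Spearman correlation of FPKM between the libraries over the 11976 genes was 0.792. With 1 library per group no p-value, standard error or replicate check can be given.

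The lists comprised 28 sets of genes: the SAGA complex, de novo lipogenesis, PPARG targets and lipid droplets, cholesterol synthesis, fatty acid oxidation, hypoxia and glycolysis, liver cancer stemness, G1 and S phase, G2 and M phase, p53 targets, MYC targets, unfolded protein and integrated stress, interferon response, NF-kappaB and inflammation, hepatocyte secretory proteins, hepatocyte transcription factors and metabolism, epithelial to mesenchymal transition and matrix, NRF2 targets, autophagy and lysosome, apoptosis regulators, immediate early genes, nuclear oxidative phosphorylation, mitochondrially encoded genes, ribosomal proteins, replication-dependent histones, and markers of blood cells, of endothelium and stroma, and of other epithelia. They were written from general knowledge. For each list with at least 5 members past the filter (26 lists), the median log2 ratio was placed among 10000 random lists of the same size drawn from the same 20 bins of mean expression, and a list stood apart below percentile 2.5 or above 97.5.

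Genes were named by a rule: USP22, PPARG, ACLY, ACACA, FASN, HIF1A, MYC and ALB; the 12 protein-coding genes with the highest and the 12 with the lowest log2 ratios at a mean of at least 5 FPKM; and up to 2 members at each end of a described list. Where 5 or fewer members of a list passed the size rule in 1 direction, those outside this rule (SUPT3H, ATXN7L3 and TAF5L in the SAGA list, for example) were named after their values were seen. Some genes that this rule would name are not reported here. The lists, the filter, the size rule, the naming rule and the first set of alternatives were fixed before the data were examined. These were pseudocounts of 0.1 and 5, median centring, TMM scaling (30% of ratios and 5% of levels trimmed at each end, unweighted), rescaling without mitochondrial genes, no filter, a mean of at least 5 FPKM, protein-coding genes only and a 1.5-fold rule.

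After the data were seen, further alternatives were added: removal of the trend with GC content by a lowess curve over a 30% span, removal of GC and length trends together, and random lists matched on 5 bins of expression and 10 of GC. Gene type, GC content and length of the longest protein-coding transcript came from GENCODE 29, matched by Ensembl identifier without its version. Identifiers matched for 11911 of the 11976 genes, and 11836 (98.8%) had a GC value. That annotation is on another build than GRCh37, so no coordinates are given, and exon overlaps of named genes were looked up within it.

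The procedure was tested on simulated pairs of libraries over 10134 genes in which 200 genes differed 4-fold and all genes carried a noise of SD 0.2 on the log2 scale, a value chosen and not measured, since the real noise is unknown. At a mean of at least 5 FPKM, the size rule found 100% of 129 genes without a GC trend. With a GC trend added and not removed it found 94.6% of 130, and 1.63% of unchanged genes passed 2-fold. With the trend removed it found 100%. The planted change was large against the chosen noise, so full recovery without a GC trend followed from the settings. In the real libraries the log2 ratios had an SD of 1.07, or 0.77 with the GC trend removed, real differences included. The simulated percentages therefore do not measure how reliable the size rule is in these libraries. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.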

Results

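Messenger RNA was profiled by RNA-seq in Huh7, an established human hepatocellular carcinoma cell line, with 1 library from cells given a control shRNA and 1 from cells given an shRNA against USP22. Each library lists the same 11976 genes, 11900 of them protein coding, with values read as FPKM that sum to 244301 in the control and 218955 in the USP22 shRNA library. The median gene stood at 3.93 FPKM in the control and 4.94 in the USP22 shRNA library, and mitochondrially encoded genes made up 17.8% and 16.9% of the summed FPKM. No read totals were used here, so the sequencing depth behind these values is unknown and no counting interval can be given. Neither group has a replicate, so no difference can be set against a replicate error, and "higher" and "lower" describe these 2 libraries only.

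The comparison asks which transcripts differ in level when USP22, the ubiquitin hydrolase of the SAGA chromatin complex, is depleted. USP22 itself (ENSG00000124422.11_2) was at 58.1 FPKM in the control and 7.67 FPKM in the USP22 shRNA library, 7.57-fold lower. Its log2 ratio, taken throughout as log2 of (USP22 shRNA + 1) over (control + 1), was -2.77, at rank 25 from the lowest of 10195 genes with a mean of at least 1 FPKM, or rank 40 of 10134 once the trend with GC content described below was removed. Among the 18 measured members of the SAGA list, which includes USP22, 3 were at least 2-fold higher and 3 at least 2-fold lower, and the list median was -0.18. The acetyltransferase KAT2B was higher, at 0.489 in the control and 3.31 FPKM in the USP22 shRNA library, as was TAF9, at 5.07 and 14.7 FPKM. TAF10 was lower, at 10.7 and 3.42 FPKM, and the remaining pair past the size rule was SUPT3H (higher) and ATXN7L3 (lower), which is a partner of USP22 in the SAGA deubiquitinase module. The SAGA median lay at percentile 18.1 of random lists matched on expression, so the complex did not stand apart from other genes. With the trend of the ratio with GC content removed, none of the members was at least 2-fold higher and 2 were lower, USP22 and TAF5L, at a median of -0.26. The other members named were then inside 2-fold, with KAT2B at 0.82, TAF9 at 0.74, SUPT3H at 0.04, TAF10 at -0.70 and ATXN7L3 at -0.82.

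Across the 10195 genes, 2454 (24.1%) were at least 2-fold higher and 1247 (12.2%) at least 2-fold lower in the USP22 shRNA library, and the median log2 ratio was 0.098. Of the genes past the size rule, 66.3% were higher, against 59.8% with ratios centred on their median and 56.5% with TMM scaling. The ratio followed GC content across genes, with a Spearman rho of -0.70 over 10134 genes, which are not independent replicates. Of 10 equal groups by GC content, in the lowest (31.1% to 39.0%) 712 of 1014 genes were higher and 3 lower, while in the highest (62.1% to 74.1%) 13 of 1013 were higher and 353 lower. With this trend removed, 856 genes were at least 2-fold higher and 904 at least 2-fold lower, or 48.6% higher, and 631 of the higher and 538 of the lower genes were the same as without the correction. Removal of the trend re-centres the ratios at each level of GC content, so a nearly even split follows largely from the method. Because of the GC trend, most lists are given with the median and counts after its removal as well, and the USP22 log2 ratio was then -2.44.

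**Figure D1:**
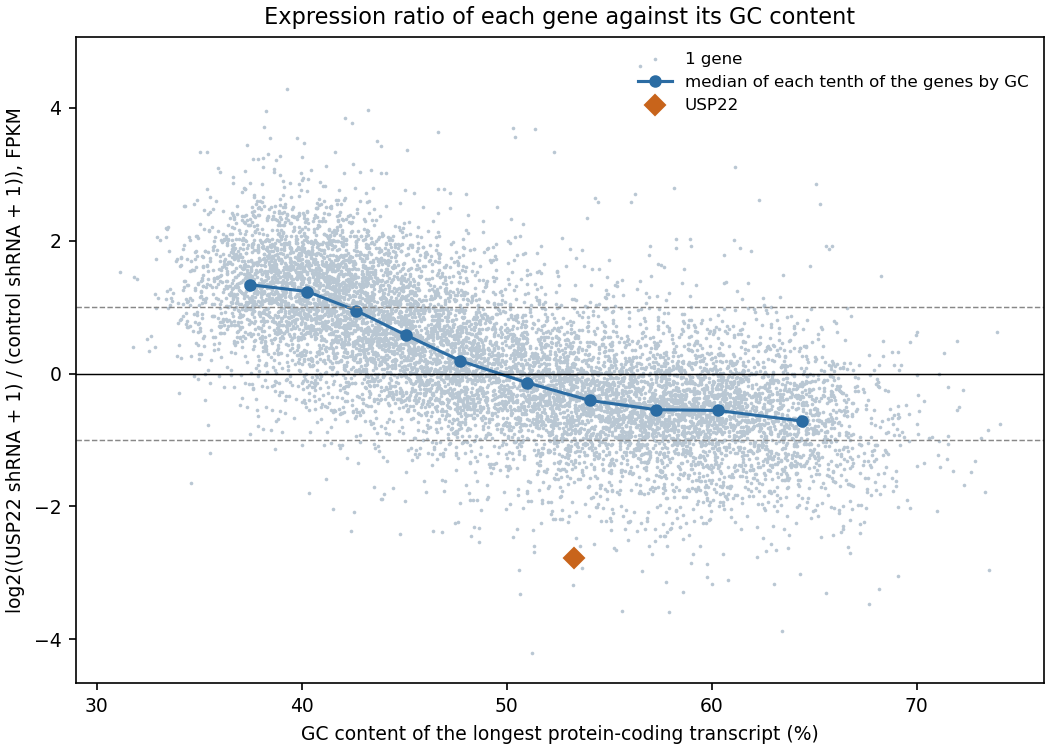
Log2 ratio of each gene between the USP22 shRNA and control libraries (vertical axis) against the GC content of its longest protein-coding transcript in percent (horizontal axis). Grey dots are single genes with a mean of at least 1 FPKM, the blue line joins the medians of 10 equal groups of genes by GC content, dashed lines mark 2-fold, and the diamond is USP22; these run from a median of 1.34 at low GC to -0.71 at high GC.

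The highest ratios among genes with a mean of at least 5 FPKM belonged to NPPB, the B-type natriuretic peptide precursor, at 18.4 FPKM in the control and 477 in the USP22 shRNA library, and ANXA1, a calcium-dependent phospholipid-binding protein, at 2.46 and 66.4 FPKM. ANKRD1, a nuclear cofactor, stood at 4.73 and 88.4 FPKM, the integrin subunit ITGAV at 6.60 and 116, and the iron exporter SLC40A1 at 8.82 and 133. CYR61, a secreted matricellular protein, was at 14.3 and 197 FPKM, the calpain subunit CAPN2 at 3.43 and 55.5, and HNRNPH2 at 0.270 and 17.2. UACA, MYOF, NRP2 and NR1D2 completed the 12 highest, with log2 ratios from 3.55 to 3.70. The order depends on the pseudocount, and with 0.1 in place of 1 HNRNPH2 (5.55), NR1D2 (5.0) and, narrowly, ANXA1 (4.70) lay above NPPB (4.69).

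At the other end, HABP2, a liver-secreted serine protease, was at 26.5 FPKM in the control and 0.482 in the USP22 shRNA library, a log2 ratio of -4.21. S100A9, a calcium-binding protein of the calprotectin complex, was at 268 and 21.5 FPKM, the mitochondrial citrate carrier SLC25A1 at 120 and 11.3, the bile acid transporter subunit SLC51B at 47.0 and 3.84, and the endocrine factor FGF19 at 52.6 and 4.50. The other 7 of the 12 lowest were REPIN1, C11orf24, SEMA6B, AL136295.4, C9orf16, SLC29A4 and JMJD8, with log2 ratios from -3.87 to -3.17. Of these 24 genes, 9 overlap exons of another annotated gene, HNRNPH2, REPIN1 and AL136295.4 on the same strand and HABP2, SLC51B, JMJD8, NRP2, ITGAV and SLC29A4 on the opposite strand. Whether strand was used in quantification is not given in the sources used here, so the values of these 9 are uncertain.

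**Figure D2:**
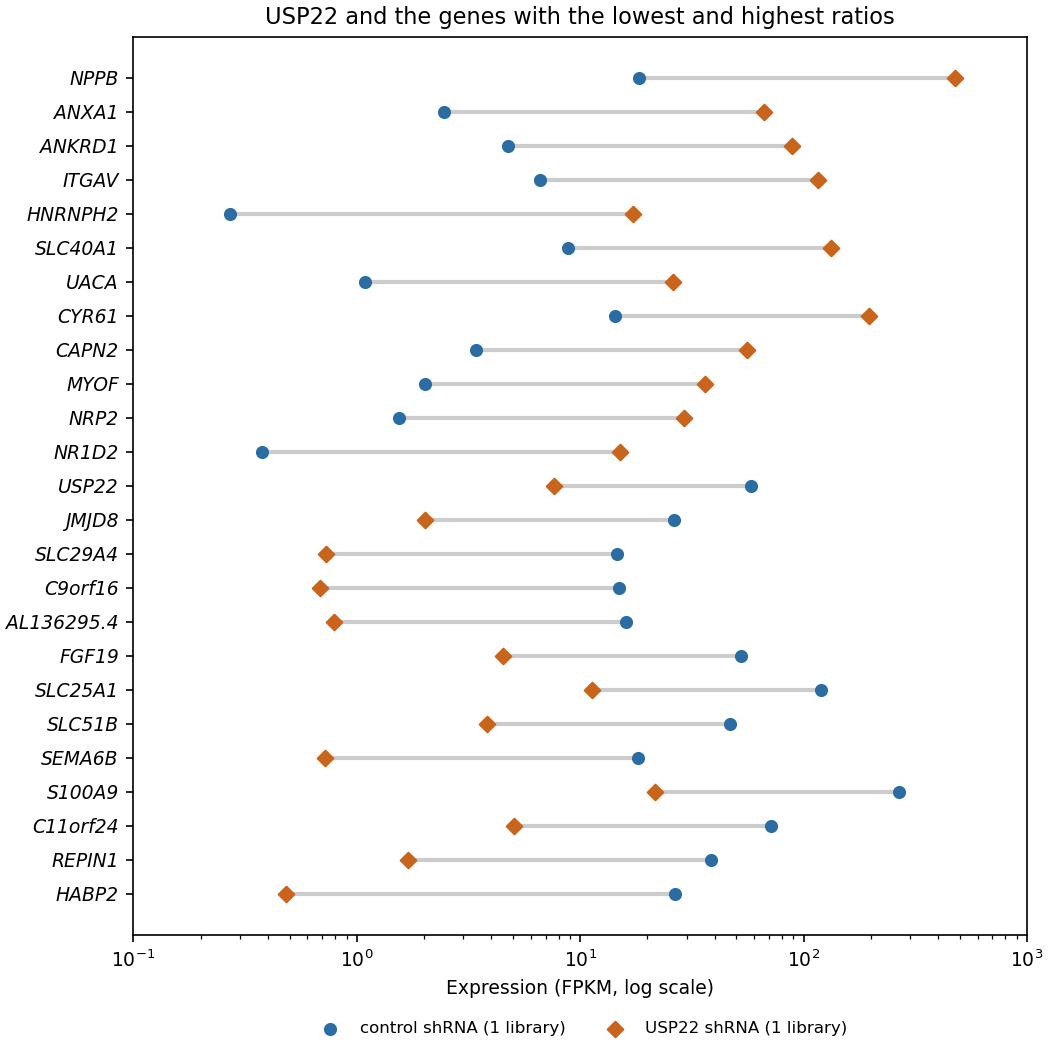
Expression in FPKM (horizontal axis, log scale) of USP22 and of the 12 genes with the highest and the 12 with the lowest log2 ratios among protein-coding genes with a mean of at least 5 FPKM (vertical axis). Circles are the control shRNA library and diamonds the USP22 shRNA library, 1 library each; USP22 lies at 58.1 and 7.67 FPKM.

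Genes that make hepatocyte secretory proteins were lower as a group. Of 27 measured members, 13 were at least 2-fold lower and 1 higher, with a median log2 ratio of -0.98. The fetuin gene AHSG was at 535 FPKM in the control and 69.3 in the USP22 shRNA library, and the thyroxine carrier TTR at 193 and 55.8. The fibrinogen gene FGG was the member at least 2-fold higher, at 49.4 and 184 FPKM, and APOB, the structural protein of very low density lipoprotein, was at 51.4 and 100. ALB was at 89.9 and 72.8 FPKM, a log2 ratio of -0.30 that became -1.40 with the GC trend removed. The median of the list lay below all 10000 random lists, both as deposited and with the GC trend removed, where it was -0.80 with 11 members lower and 1 higher.

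Liver transcription factors and metabolic enzymes were also lower, with 6 of 16 members at least 2-fold lower, none higher and a median of -0.62 at percentile 0.88. CEBPA, a transcription factor of hepatocyte differentiation, was at 267 FPKM in the control and 48.9 in the USP22 shRNA library, and the urea cycle enzyme ARG1 at 8.59 and 0.849. Another urea cycle enzyme, ASS1, was at 22.6 and 37.8 FPKM, and FOXA1 at 13.6 and 16.6. The median was -0.54 with the GC trend removed, with 6 members lower and 1 higher. The list did not stand apart against random lists matched on GC content as well as expression (percentile 10.5), with a mean of at least 5 FPKM (14.8) or with no filter on low values (3.49).

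Genes of de novo lipogenesis were lower as a group, with 8 of 18 members at least 2-fold lower, 3 higher and a median of -0.69 at percentile 0.61. SLC25A1, which exports citrate from mitochondria, and ACLY, which cleaves it to acetyl-CoA, had the lowest ratios, and ACLY stood at 91.7 FPKM in the control and 20.3 in the USP22 shRNA library. Fatty acid synthase, FASN, was at 193 and 58.2 FPKM, a log2 ratio of -1.71 that was -0.98 with the GC trend removed. The carboxylase ACACA was at 7.59 and 6.44 FPKM. The higher members were LPIN1, at 1.08 and 5.67 FPKM, ELOVL6, at 2.5 and 6.99, and GPAM. After removal of the GC trend the list median was -0.52 at percentile 0.86, with 5 members lower and 1 higher, and ELOVL6 (0.08) and GPAM (0.07) were no longer past 2-fold.

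Cholesterol synthesis genes were higher as a group, in contrast to those of fatty acid synthesis, with 8 of 22 members at least 2-fold higher, 2 lower and a median of 0.45 at percentile 99.7. The sterol oxidase MSMO1 was at 18.9 FPKM in the control and 124 in the USP22 shRNA library, and HMGCS1, an early enzyme of the mevalonate pathway, at 42.8 and 211. Once the GC trend was removed the median was 0.40 with 4 members at least 2-fold higher and 2 lower.

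PPARG, a nuclear receptor of lipid storage, was at 13.2 FPKM in the control and 12.9 in the USP22 shRNA library, a log2 ratio of -0.02 that was 0.11 when values were rescaled without mitochondrial genes and -0.78 with the GC trend removed. The 13-member list of its targets and lipid droplet genes includes PPARG, whose own ratio was the median of the list, -0.02 at percentile 55.5. ACSL3, at 7.19 and 22.2 FPKM, and ANGPTL4, at 2.36 and 6.47, were higher, and FABP1, at 149 and 60.5, and RXRA, at 17.7 and 7.14, were lower. Removal of the GC trend gave a median of -0.12, and ANGPTL4 (1.83) was the higher member and FABP1 (-1.66) the lower. In fatty acid oxidation, 3 of 20 members were higher (ACADM, EHHADH and ETFDH) and 4 lower (among them ECI1, ETFB and ACADVL), with a median of -0.14 at percentile 29.7. After removal of the GC trend none was higher and 3 were lower at a median of -0.30, and ACADM (0.57), EHHADH (0.49) and ETFDH (0.35) were inside 2-fold.

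Genes of the unfolded protein and integrated stress responses were higher, with 12 of 24 members at least 2-fold higher, 2 lower and a median of 1.0, above all 10000 random lists. The cystine transporter SLC7A11 was at 0.451 FPKM in the control and 13.6 in the USP22 shRNA library, and the endoplasmic reticulum co-chaperone DNAJB9 at 3.86 and 39.7. The lower members were SDF2L1, at 69.0 and 20.2 FPKM, and the disulfide isomerase PDIA4, at 183 and 84.0. With the GC trend removed the median was 0.77, with 9 members at least 2-fold higher and none lower.

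Genes of G2, M phase and the spindle were higher, with 15 of 25 members at least 2-fold higher, none lower and a median of 1.07, above all 10000 random lists. Topoisomerase TOP2A was at 6.81 FPKM in the control and 53.4 in the USP22 shRNA library, and the kinetochore protein CENPF at 1.27 and 13.0. AURKB, at 43.4 and 21.7 FPKM, and BIRC5, at 16.0 and 8.07, both of the chromosomal passenger complex, had the lowest ratios. Members of this list were low in GC content, at a median of 43.2%. After removal of the GC trend 6 were at least 2-fold higher and none lower at a list median of 0.66, and against lists matched on GC the percentile was 97.6, close to the edge of the central 95%.

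Genes of G1, S phase and replication did not stand apart, with a median of -0.40 at percentile 8.45 over 25 members. The higher members were CDK6, at 0.605 and 7.97 FPKM, and CCNE2, at 0.195 and 2.91. The lower ones were the transcription factors E2F1, at 57.6 and 9.60 FPKM, and E2F2, at 6.79 and 0.982, with GINS2, MCM2 and CDK2. Their median was -0.17 after removal of the GC trend, with 1 member higher and 5 lower. Replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail and are poorly captured where poly(A) tails are selected, were lower, with 8 of 14 members at least 2-fold lower, none higher and a median of -1.16, below all 10000 random lists. HIST1H1C was at 222 and 40.1 FPKM and HIST2H2AA4, which has a near-identical copy, at 42.2 and 8.81, while HIST1H2BC was at 4.23 and 6.50 and HIST1H3B at 1.15 and 1.40. The histone median was -1.11 with the GC trend removed, with 8 members lower and none higher.

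Genes of the matrix and of epithelial to mesenchymal transition were higher, with 7 of 16 members at least 2-fold higher, none lower and a median of 0.39 at percentile 98.1. CYR61 had the highest ratio, followed by the collagen chain COL1A1, at 11.1 FPKM in the control and 104 in the USP22 shRNA library. The transcription factor SNAI1, at 12.8 and 7.44 FPKM, had one of the lowest ratios in the list. The median was 0.90 with the GC trend removed, above all 10000 random lists, with 8 members higher and none lower. With no filter on low values the list lay at percentile 96.5, inside the range of random lists.

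**Figure D3:**
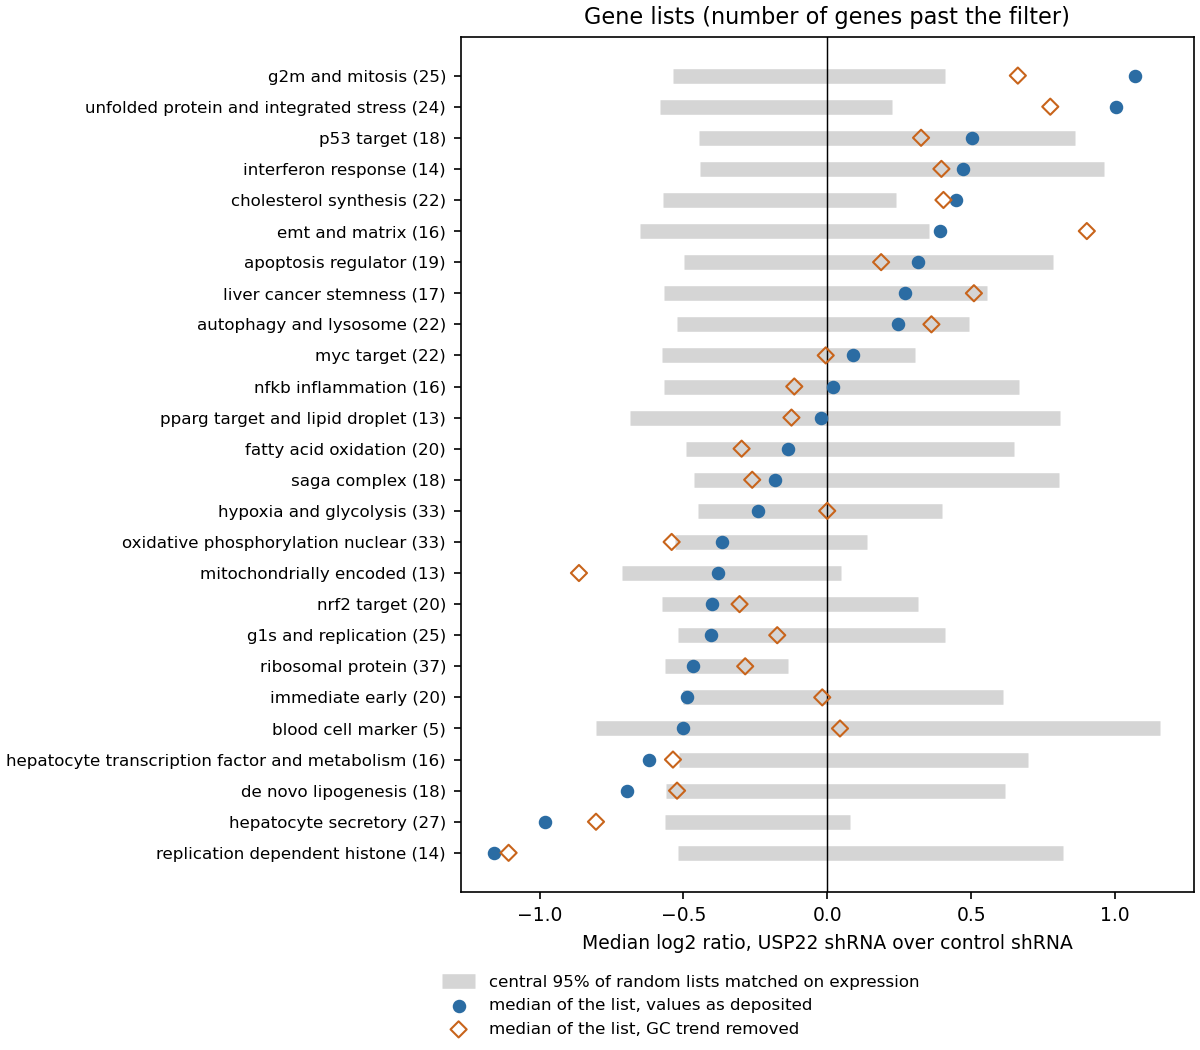
Median log2 ratio (horizontal axis) of each of the 26 gene lists with at least 5 measured members (vertical axis, number of members in brackets). Filled circles are medians of the deposited values, open diamonds medians with the GC trend removed, and grey bars the central 95% of 10000 random lists of equal size matched on expression, for the deposited values; the medians run from -1.16 for replication-dependent histones to 1.07 for G2 and M phase.

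In all, 8 of the 26 lists with at least 5 measured members stood outside the central 95% of their random lists, 4 higher and 4 lower, where the rule alone gives 1.3 for independent lists. Each of the 8 also stood apart with the GC trend removed. Against lists matched on GC as well as expression 7 of the 8 did, and hepatocyte transcription factors and metabolism, at percentile 10.5, did not. The percentiles describe these libraries and are not tests, because genes are not replicates and some lists share members.

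The remaining lists of at least 5 measured members lay within the range of random lists as deposited. HIF1A was at 3.95 FPKM in the control and 18.3 in the USP22 shRNA library, a log2 ratio of 1.96 that was 0.61 with the GC trend removed. Of 33 hypoxia and glycolysis genes, 8 were higher, among them the mitophagy receptor BNIP3L, at 4.26 and 29.6 FPKM, and the glucose transporter SLC2A3, at 0.267 and 4.25. PFKFB4, at 5.50 and 1.45 FPKM, ALDOC, at 18.7 and 6.79, and PFKL were lower, and the median was -0.24 at percentile 21.6. That median was -0.00066 with the GC trend removed, with 5 members higher and 1 lower. MYC was at 15.8 and 6.17 FPKM, a log2 ratio of -1.23 that was -0.86 with the GC trend removed and -0.90 with a pseudocount of 5. The MYC target list had a median of 0.09 at percentile 89.3, with TFRC, NOP58, WDR43 and GNL3 higher and FBL, NOP16, MYBBP1A and BOP1 lower among 22 members. Removal of the GC trend gave -0.01 over 21 members, with 1 higher and none lower.

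In the liver cancer stemness list, 5 of 17 members were higher and MYC was lower, with a median of 0.27 at percentile 88.4. BMI1 was at 0.850 and 8.95 FPKM, ABCG2 at 6.17 and 23.5, and KRT19 at 290 and 192, and the other higher members were ALDH1A1, PROM1 and CD44. After removal of the GC trend BMI1 (1.16) was the member at least 2-fold higher and none was lower, while the median was 0.51, above the central 95% of random lists. As deposited and against lists matched on GC, the stemness list lay at percentile 77.2 and did not stand apart. In the p53 target list 6 of 18 members were higher, with TP53INP1 at 1.40 and 11.5 FPKM and RRM2B at 0.762 and 4.63, while AEN was lower at 17.0 and 2.84, and the median was 0.50 at percentile 83.3, against 0.33 with the GC trend removed, where 5 were higher and 1 lower. The sign of the p53 target median depends on the filter, as it was -0.47 at percentile 11.4 with a mean of at least 5 FPKM. Apoptosis regulators had a median of 0.32 at percentile 75.4 over 19 members, with 5 higher, among them PMAIP1, APAF1, MCL1 and BIRC2, and the anti-apoptotic BCL2L1, at 166 and 47.3 FPKM, and BAD lower. Their median was 0.19 with the GC trend removed, with 2 higher and 1 lower. Of 14 interferon response genes 6 were higher, among them IFIT3 at 0.216 and 2.88 FPKM, none was lower, and the median was 0.47 at percentile 72.5, against 0.40 with the GC trend removed, where 3 were higher and none lower.

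NF-kappaB and inflammation genes had a median of 0.02 at percentile 58.8 over 16 members, with TNF, at 1.31 and 13.4 FPKM, TNFAIP3 and CXCL8 higher and LCN2 and CXCL1 lower, and with the GC trend removed -0.12, with 4 higher and 2 lower. NRF2 targets had a median of -0.40 at percentile 15.4 over 20 members, with SLC7A11, GCLC, GCLM and TXNRD1 higher and AKR1B10, at 28.1 and 5.11 FPKM, SRXN1 and FTH1 among the 4 lower. That median was -0.31 with the GC trend removed, with 1 higher and 5 lower. Among 22 autophagy and lysosome genes, 5 were higher, among them CTSL, ATG5, LAMP2 and GABARAPL1, and none lower, with a median of 0.25 at percentile 89.3. With the GC trend removed 3 were higher and none lower, and the median, 0.36, lay above the central 95% of random lists, whereas against lists matched on GC the percentile was 95.9. Immediate early genes had a median of -0.49 at percentile 2.85 over 20 members, with KLF6, ATF3 and KLF10 higher and SPRY4, JUND, EGR1, MYC and DUSP5 lower. Their median was -0.02 with the GC trend removed, with 4 higher and 3 lower.

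No nuclear gene of oxidative phosphorylation among 33 measured passed the size rule in either direction, and the median was -0.37 at percentile 18.7. With the GC trend removed 7 of the 33 were at least 2-fold lower and none higher, and the median of -0.54 lay at percentile 0.09, below the range of random lists. Of 13 mitochondrially encoded genes, MT-ATP6 was higher and none lower, with a median of -0.38 at percentile 49.6. After removal of the GC trend 5 of these were lower and 1 higher, and the median of -0.86 lay at percentile 0.27. Among 37 ribosomal protein genes RPLP0, at 327 and 144 FPKM, was lower and none higher, with a median of -0.47 at percentile 16.5, and with the GC trend removed the median was -0.29, with 4 lower and none higher. Of the markers of other cell types, 5 of the 15 blood cell genes listed were measured past the filter, with a median of -0.50 at percentile 10.3 and LYZ, at 386 and 93.6 FPKM, and CD68, at 3.88 and 0.416, lower. The blood cell median was 0.04 with the GC trend removed, with 2 lower and none higher. In the endothelial and stromal list LUM was at 1.37 and 8.95 FPKM and PDGFRB at 1.68 and 1.31, with log2 ratios of 0.72 and 0.33 once the GC trend was removed. In the list of other epithelia, the intestinal genes VIL1, at 94.9 and 28.1 FPKM, and CDX2, at 16.5 and 2.39, were lower, also with the GC trend removed (-2.41 and -1.87).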

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

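USP22 stayed lower under each alternative run, with log2 ratios from -2.93 (TMM scaling) to -2.32 (pseudocount of 5). The number of genes at least 2-fold higher, 2454 as reported, was 888 with a pseudocount of 5, 1184 with a mean of at least 5 FPKM, 856 with the GC trend removed and 828 with GC and length trends removed. The number at least 2-fold lower, 1247 as reported, was 534 with a pseudocount of 5, and 2464 genes were at least 1.5-fold lower. The stricter settings test fewer genes or shrink low ratios by construction. Candidate sources of the GC trend are examined below, and its cause stays open. The median log2 ratio of all genes, 0.098, was -0.05 with TMM scaling and 0.22 when rescaled without mitochondrial genes, where 73.1% of genes past the size rule were higher.

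The number of lists standing apart, 8 as reported, was 12 with the GC trend removed and 13 with GC and length trends removed, and the cause of that difference was not tested. Of the 8, hepatocyte transcription factors stood apart in 8 of 11 settings and the matrix list in 10, while the other 6 did so in all 11, and no median of the 8 changed sign. Median centring shifts all genes alike and so cannot change a percentile. TMM scaling, rescaling without mitochondrial genes and the limit to protein-coding genes could change percentiles only slightly. These settings are therefore weak checks of whether a list stands apart. The lists added by removing the GC trend were liver cancer stemness (0.51) and autophagy (0.36), higher, and nuclear oxidative phosphorylation (-0.54) and mitochondrially encoded genes (-0.86), lower. Against lists matched on GC, p53 targets lay at percentile 99.1, NRF2 targets at 1.26, ribosomal proteins at 2.04, nuclear oxidative phosphorylation genes at 0.07 and mitochondrially encoded genes at 0.16, while stemness (77.2), autophagy (95.9) and hepatocyte transcription factors (10.5) did not stand apart. Among lists that did not stand apart, the sign of the median differed in some settings. MYC targets were at -0.09 and NF-kappaB genes at -0.13 with TMM scaling, PPARG targets at 0.11 when rescaled without mitochondrial genes and the SAGA list at 0.06 with no filter. With a mean of at least 5 FPKM the p53 targets were at -0.47 and the stemness list at -0.03. Immediate early genes lay at percentile 1.56 with a pseudocount of 0.1 and interferon response genes at 98.8 with no filter. The GC and length alternatives and the lists matched on GC were chosen after seeing the data. No paired analysis was possible because each group holds 1 library, and for the same reason no library could be left out. Unknown depth limits the genes near the filter most, since their counting error cannot be computed.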

Other observations

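The 10 further gene lists given here and every test in this part were chosen after the result was seen, except the test of GC recovery on ribosomal and oxidative phosphorylation genes and the comparison of COL1A2 with COL1A1.

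Known targets of the YAP and TAZ coactivators were higher in the USP22 shRNA library, with 11 of 19 measured members at least 2-fold higher, none lower and a median log2 ratio of 1.15. With the GC trend removed 12 were higher, ASAP1 (-1.17) was lower and the median was 1.3. The clotting initiator F3 was at 3.43 FPKM in the control and 48.9 in the USP22 shRNA library, CRIM1 at 2.75 and 20.1, and CTGF at 44.4 and 109. Because 3 members, ANKRD1, CYR61 and MYOF, prompted the list, it was run again without them, giving a median of 0.96 over 16 genes at percentile 98.8. Reruns of this kind, here and below, do not undo the choice of a list after the ratios were seen. Genes of the actin cytoskeleton, many of them SRF targets, had a median of 0.67 over 24 members, with 10 higher and 2 lower. TAGLN was at 11.2 and 78.5 FPKM, FLNC at 10.1 and 66.9 and CALD1 at 3.34 and 42.5, whereas ACTB was lower at 1036 and 374, as was ZYX at 41.5 and 18.0. After removal of the GC trend 13 were higher and none lower at a median of 1.07, and ACTB (-0.98) and ZYX (-0.44) were inside 2-fold. Integrins had a median of 1.67 over 7 members with 4 higher, but this was 0.61 with 2 higher once the GC trend was removed, inside the range of random lists (percentile 97.0). Against lists matched on GC, the integrin median as deposited lay at percentile 99.1. Without ITGAV, which prompted the list, the percentile as deposited was 93.9, and annexins without ANXA1 lay at 91.1.

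Aminoacyl-tRNA synthetases, several of which are induced in amino acid stress, had 7 of 20 members higher, none lower and a median of 0.42 at percentile 97.9 (93.0 against lists matched on GC), with EPRS at 8.08 and 53.2 FPKM. Their median was 0.37 with 3 higher and none lower once the GC trend was removed. Chaperonin and heat shock genes had 7 of 21 higher, none lower and a median of 0.75, or 2 higher, none lower and 0.28 with the GC trend removed, with HSP90AA1 at 46.4 and 229 FPKM and its paralog HSP90AB1 at 720 and 466. Genes of iron and bile acid handling had 7 of 14 lower and 2 higher, with a median of -0.82, or 8 lower, 2 higher and -1.10 with the GC trend removed. The iron regulator HAMP was at 42.5 and 4.56 FPKM, SLC51A, partner of SLC51B, at 4.06 and 0.517, and TFRC at 23.1 and 105. Without the 3 genes that prompted it, that list lay at percentile 8.79, with a median of -0.46 (-1.04 with the GC trend removed, below all 10000 random lists). Proteasome subunits (median 0.07, or -0.05 with the GC trend removed), mitochondrial ribosomal proteins (-0.28) and core splicing factors (-0.39) did not stand apart as deposited, although the splicing factors did with the GC trend removed (-0.41). MT-ATP6 was at 1108 FPKM in the control and 3817 in the USP22 shRNA library while MT-ATP8, which overlaps it, was at 6473 and 4081.

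The log2 ratio was lower at higher GC content across the transcriptome. Transcript length is argued against as its whole source, since the median rho with GC within 5 classes of length was -0.69, with each class between -0.73 and -0.52. A candidate explanation is unequal recovery of fragments by GC content in the preparation or sequencing of 1 of the libraries. Over 70 ribosomal protein and nuclear oxidative phosphorylation genes, which are usually expressed as groups, rho was -0.58 (bootstrap 95% interval over genes -0.72 to -0.41), as such a bias would give. The interval resamples genes within 1 pair of libraries and does not measure variation between libraries. A GC-linked effect of the knockdown itself could give the same rho, so this test does not separate it from such a bias. That effect stays open and untested with 1 library per group, and removing the trend would also remove it.

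The matrix and mesenchymal list was higher, and the GC trend is argued against as the whole cause, since with it removed the median was 0.90, outside the -0.48 to 0.31 of random lists. Stromal cells in the culture were examined through COL1A2, which fibroblasts express at about the level of COL1A1: it was at 13.2% of COL1A1 in the USP22 shRNA library, between the limits set for the test, so a small admixture cannot be told apart from none. As the source of the added COL1A1 they are argued against, since COL1A2 and COL3A1 together were 2.67 FPKM above the control and COL1A1 92.5 FPKM above it, a share of 2.89%, although COL1A2 in the control, at 11.2, was as high as COL1A1, at 11.1. Other genes that stromal cells express differed in direction, with LUM at 1.37 and 8.95 FPKM, SPARC at 9.31 and 67.0 and VIM at 43.2 and 130 higher, FN1 lower at 352 and 275, and ACTA2 listed at 0 in both libraries. An effect of USP22 depletion may be at work, as may cell density or an off-target effect of the shRNA, none of which was tested.

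The hepatocyte secretory list was lower, and the GC trend is argued against as the whole cause, since with it removed the median was -0.80, outside the -0.41 to 0.14 of random lists. A smaller share of hepatocyte-type cells, which would lower the members by a shared factor, stays open, as neither prediction was met. With the GC trend removed the log2 ratios of the 27 members ran from -2.58 to 1.33. Of these, 7 lay above 0, 4 of them also as deposited, where a smaller share was predicted to leave at most 1. The members' interquartile range of 1.21 was inside the 0.473 to 1.26 of random lists, at percentile 95.5. The range cannot decide, because a fit asked for one below random lists while a shared factor would leave the spread as it is. Earlier forms of this test were replaced after they were seen: the 10 most abundant members alone, all lower with an interquartile range of 0.57 as deposited, decided nothing, and all members judged without random lists had spoken against a smaller share. Lower expression of these genes after USP22 depletion may be the cause, but with 1 library per group a difference between cultures is open too.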
